A study of Homo sapiens with 272 samples.

How the data were processed

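Cell-free RNA was measured in plasma and urine of healthy volunteers, HSCT recipients and patients with AKI under immune checkpoint inhibitor therapy. The data were 1 deposited table of gene counts with 60708 genes and 272 count columns. Per the labels, plasma was extracted with a Norgen kit and urine, spun faster, with a Qiagen kit. Per the labels, libraries were made with a Takara stranded total RNA kit for low input and read on Illumina NextSeq machines. Reads were mapped to GRCh38, and Picard and SAMtools 1.14 were used, per the submitters' processing notes, while the aligner and the counting tool are not given in the sources used here. The deposited counts were taken as raw counts, since every value was a whole number.

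Columns were joined to labels by sample name, except in healthy plasma. Titles there carried the letter u of the urine names, so columns with the letter p and the same number were used. That p stands for plasma was assumed. There were 97 HSCT plasma names that stood at 2 columns each with identical counts in both, and 1 of each was kept, which left 175 libraries and 97 columns not used. The 97 labelled HSCT urine samples had no column of their own name and were not analysed here, so 10 comparisons planned with them were not run, nor was the alternative of leaving out the 1 of them whose source name gave the other fluid. Gene identifiers were joined to GENCODE 29 (58440 found, 60463 with a symbol), and 56947 genes had at least 1 count.

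Groups were formed by fluid, cohort and time label, namely PR, D0, E, 1M, 2M, 3M and 6M in HSCT and TP1 and TP2 in AKI, whose meaning the labels do not spell out. The times were assumed to follow in the order listed. Patients were not labelled, so no blocking by patient was possible. Healthy plasma and urine titles carried the same numbers. The correlation of gene residuals between equal numbers was 0.041, 0.002, 0.06, 0.04 and 0.08, none over 0.1 and the own number closest in 2 of 5. They were not treated as pairs in the main fit. The check does not rule pairs out, since 2 fluids of 1 donor may also correlate little. Duplicate libraries were checked by a chi-square per gene between all pairs within a group, whose lowest value was 3.41, so no pair differed by counting noise alone. The median library held 843042 counts, and 102 of 175 held fewer than 1000000.

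Differences were tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1), using TMM scaling, filterByExpr (min.count 10, min.total.count 15, large.n 10, min.prop 0.7), quasi-likelihood F tests and Benjamini-Hochberg adjustment with a threshold of 0.05. The 13 comparisons were urine against plasma in healthy volunteers and in AKI, any difference over time in HSCT plasma, D0 against PR, E against D0, E against PR and 6M against PR in HSCT plasma, TP2 against TP1 in AKI urine and in AKI plasma, the difference of those changes between fluids, AKI against healthy in urine and in plasma, and PR against healthy in plasma. HSCT contrasts came from 1 model of the 7 times, the AKI fluid contrast held the time label as a covariate, TP2 and TP1 were fitted within each fluid, the difference of changes came from 1 model of the 4 AKI groups, and AKI against healthy was the mean of TP1 and TP2 minus healthy. Standard errors were the absolute log2 difference over the square root of F.

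There were 23 gene lists fixed from general knowledge before the data were examined, for neutrophil, granulocyte precursor, monocyte and macrophage, T cell, cytotoxic lymphocyte (NK), B and plasma cell, erythroid, platelet, proximal tubule, distal nephron, collecting duct, podocyte, tubular injury, urothelial, squamous, hepatocyte, endothelial, type I interferon, interferon gamma, proliferation, p53 target, mitochondrial protein and ribosomal protein genes. A library's list score was the mean of log2(TMM CPM + 1) over the list's genes found in the table. Scores were compared by two-sided permutation of the group labels, all regroupings (exact) where a group held fewer than 10 libraries and 100000 random ones otherwise, within fluid for the difference of changes, with Benjamini-Hochberg adjustment over the 23 lists. Measured members, those that met the expression filter, were counted as passing after adjustment over all genes tested and again after adjustment over the list alone.

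Genes were named by a rule fixed beforehand, the 8 largest rises and 8 largest falls in log2 difference with an adjusted p under 0.05 and a mean of at least 20 CPM, and the 2 members of each list with the smallest p. For the test of any difference over time the smallest p values were named. XIST, TSIX, Y-linked genes and symbols shared by many copies were not named. A few other genes that met the rule are not reported here. Where 1 group had 0 counts a gene's difference is given as at least a fold, from a floor of 3 counts over the group, and where it had 1 to 3 counts as a ratio with its 95% counting interval, which covers counting error only because the counts are of amplified reads. These folds and ratios are of pooled counts over total counts, without TMM scaling. Mean TMM factors were 1.28 in AKI urine and 0.81 in AKI plasma, and 1.15 and 0.88 in healthy volunteers. Folds higher in urine are thus larger than with scaling, and folds higher in plasma smaller.

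The procedure was tested on simulated data, negative binomial counts with the group sizes, depths and dispersions of each comparison and 200 changed genes. The changed genes were drawn from those with a mean of at least 20 CPM. Libraries were simulated as independent, so the shares found do not hold for weaker genes or repeated donors. Changes of 2-fold and 4-fold were found in 15% and 77% for fluid in healthy volunteers, 92% and 98% for fluid in AKI, 65% and 94% for any difference over time, 59% and 96% for D0 against PR, 57% and 96% for E against D0 and 63% and 97% for E against PR. They were found in 30% and 81% for AKI against healthy urine, 46% and 97% for AKI against healthy plasma and 13% and 87% for PR against healthy plasma. The share of false calls ran from 0.625% to 6.12%, with 0 calls of the wrong sign. These shares and the shares found describe the simulated counts only, which held no structure among libraries beyond depth and group. Other splits of the real libraries, which can carry part of the real difference, passed up to 653 genes for AKI against healthy urine and 1231 for plasma. False calls in the real data can thus be more frequent than in the simulated data.

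Alternatives were no expression filter (total count of at least 10), total-count scaling in place of TMM, fits of only the 2 groups compared, DESeq2 1.42.0, libraries under 1000000 counts left out, each healthy library left out in turn (1 replicate number in both fluids for the fluid comparison), the healthy numbers as pairs, and for scores a pseudocount of 5, total-count CPM and the log2 of summed CPM. Added after the data were seen were leaving out mitochondrial and RN7SL genes, leaving out libraries with over 500 olfactory receptor CPM, the olfactory receptor share (log2 after adding 10) as a covariate, single healthy libraries left out for scores, and scores at 1M, 2M and 3M against PR. Groups were also split in other ways to see how many genes passed, and 56 measures of the healthy groups were tested for an outlying library by Dixon's ratio. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.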

Results

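Cell-free RNA from urine and from plasma was compared across 175 libraries, each carrying a deposited gene count. The libraries came from healthy volunteers (5 of plasma, 5 of urine), recipients of hematopoietic stem cell transplantation, written HSCT (97 of plasma), and patients with acute kidney injury under immune checkpoint inhibitor therapy, written AKI (34 of plasma, 34 of urine). The 97 labelled HSCT urine samples were not analysed here. Differences are log2 differences with the standard error of the fit, urine, the later time or the patients first. Levels are group means with standard deviation in the same order, in CPM (counts per 1000000 after TMM scaling within each comparison). The level of 1 group can thus differ between comparisons. Folds with a counting interval or given as at least a fold are without TMM scaling and can differ from the levels beside them. Counts of libraries on 1 side are against the median of the other group. A list score is the mean log2(CPM + 1) over the genes of 1 of 23 fixed lists. All tests were two-sided, and genes are given with Ensembl identifier and GRCh38 position, protein coding in GENCODE 29 unless another type is stated. Apart from the equal numbers of the healthy fluids, labels did not tell which libraries came from the same donor, so p-values measured the spread between libraries.

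Library totals ran from 180053 to 4115441 counts in AKI plasma, from 91822 to 8402092 in HSCT plasma and from 579732 to 1558164 in healthy plasma. Urine totals ran from 96218 to 4801309 in AKI and from 78501 to 3736892 in healthy volunteers, and 102 of the 175 libraries held fewer than 1000000 counts. Mitochondrial ribosomal RNA took up 15.5 ± 8.05% of counts in AKI plasma, 13.3 ± 8.44% in HSCT plasma and 8.23 ± 4.47% in healthy plasma, against 0.410 ± 0.710% in AKI urine and 1.70 ± 3.31% in healthy urine. Olfactory receptor genes, taken as a rough gauge of background although some are expressed in kidney or red cell precursors, had a median of 182.3 CPM in healthy urine, 146.6 in healthy plasma, 17.9 and 19.7 in AKI urine at TP1 and TP2, and 25.1 and 51.8 in AKI plasma. For these genes CPM is per 1000000 counts outside mitochondrial genes, without TMM scaling.

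Healthy urine carried RNA of the kidney tubule and the urinary lining, and healthy plasma carried RNA of blood cells (5 libraries each). EVPL (ENSG00000167880.8, chr17:76004502-76027452), envoplakin of the cell envelope of lining epithelium, was 9.70 ± 0.64 log2 units higher in urine (3730 ± 1755 against 5.06 ± 4.15 CPM). CCL5 (ENSG00000271503.6, chr17:35871491-35880793), a chemokine released by T cells and platelets, was 1837-fold (95% counting interval 628 to 8912) higher in plasma (0.904 ± 1.30 against 1180 ± 710.4 CPM). CD37 (ENSG00000104894.12, chr19:49335171-49343335), a tetraspanin of B cells, had 1919 counts in plasma and 0 in urine, at least 539.5-fold more.

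By edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, 4141 of 9939 genes passed at 0.05, 1926 higher in urine and 2215 lower (2810 and 1584 with total-count scaling). The adjusted edgeR quasi-likelihood p (Benjamini-Hochberg) was 3.09e-08 for EVPL, 6.72e-08 for CCL5 and 8.16e-08 for CD37. All 5 urine libraries lay on the stated side of the plasma median for these 3 genes. MLPH, a linker of granules to motors, was 10.05 ± 0.80 higher in urine and PPL, periplakin, 9.64 ± 1.33 higher. The urothelial transcription factor GRHL3 was 938-fold (95% counting interval 321 to 4553) higher, and SFN, EPN3 and HAO2, with 0 counts in plasma, were at least 301-fold, at least 249.8-fold and at least 72.3-fold higher. Plasma exceeded urine by at least 649-fold for GIMAP7, a lymphocyte GTPase, by at least 405-fold for the lymphocyte adapter SASH3, by at least 398-fold for CD52 and by 2844-fold (95% counting interval 510.1 to 112400) for RGS18 of platelets. HBA2 (at least 2465-fold), IGHM (at least 317-fold) and the transcribed pseudogene CXCR2P1 (at least 301-fold) were also higher in plasma.

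Blood cell lists were lower in urine in all 5 libraries, by exact permutation tests whose Benjamini-Hochberg adjusted p of 0.0122 over the 23 lists was the smallest they could give. Scores fell from plasma to urine for erythroid genes (0.94 ± 0.45 against 6.70 ± 0.68), platelet (1.16 ± 0.56 against 6.84 ± 0.83), T cell (0.53 ± 0.53 against 5.23 ± 0.69), cytotoxic lymphocyte (0.48 ± 0.56 against 4.86 ± 0.37) and B cell genes (0.53 ± 0.63 against 4.32 ± 0.36). The same held for neutrophil (1.19 ± 1.31 against 4.82 ± 0.25), monocyte (1.15 ± 0.66 against 4.93 ± 0.29) and granulocyte precursor genes (0.45 ± 0.37 against 2.44 ± 0.92), although no granulocyte precursor gene met the expression filter and the neutrophil score did not pass with summed CPM (-4.66, adjusted p = 0.1043). Of the measured genes, 10 of 11 erythroid, 13 of 13 platelet, 11 of 11 T cell, 8 of 8 cytotoxic, 6 of 6 B cell, 6 of 8 neutrophil and 8 of 8 monocyte genes passed as lower in urine, the same counts when adjusted over the list alone. Endothelial (1.139 ± 0.72 against 4.51 ± 0.47), type I interferon (3.14 ± 0.40 against 5.39 ± 0.34), interferon gamma (3.24 ± 0.58 against 5.31 ± 0.20) and proliferation scores (1.06 ± 0.30 against 3.66 ± 0.53) were lower too. Urothelial (6.04 ± 0.98 against 1.13 ± 0.41), proximal tubule (4.01 ± 1.53 against 1.05 ± 0.43) and collecting duct scores (3.35 ± 0.77 against 0.62 ± 0.23) were higher in urine. Passing genes numbered 7 of 7, 4 of 4 and 3 of 3, from lists of 12, 15 and 12 genes. Measured genes are those that met the expression filter, and a gene nearly absent from 1 fluid met it only through the other. Such counts of passing genes therefore add little to the list scores. KRT8, a keratin of simple epithelium, was 8.51 ± 0.53 higher in urine (1703 ± 567 against 4.30 ± 3.29 CPM), and SCNN1G, a sodium channel subunit of the collecting duct, was 527-fold (95% counting interval 146 to 4359) higher.

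Distal nephron genes scored 3.25 ± 1.24 against 1.13 ± 0.37, squamous genes 3.91 ± 3.61 against 0.67 ± 0.17, hepatocyte genes 0.76 ± 0.25 against 1.38 ± 0.48, mitochondrial protein genes 6.82 ± 2.09 against 10.45 ± 1.02 and ribosomal protein genes 9.72 ± 0.75 against 10.75 ± 0.27. Their exact permutation adjusted p were 0.0203, 0.0274, 0.0274, 0.0203 and 0.0203. Podocyte (-0.20, adjusted p = 0.603), tubular injury (0.99, adjusted p = 0.0609) and p53 target scores (-0.36, adjusted p = 0.407) did not pass the exact permutation test. With summed CPM the hepatocyte difference (-0.29) no longer passed, and podocyte (-2.58) and tubular injury differences (2.63) did. With a pseudocount of 5 and with total-count CPM the hepatocyte difference was -0.18 and -0.50, no longer passing, and the tubular injury difference 0.94 and 1.27, passing. The ribosomal difference was -0.63 with total-count CPM, no longer passing. Urine and plasma differed in kit and spin speed, so fluid cannot be told from extraction. HBA2 and IGHM share reads with near-identical genes. No squamous gene met the expression filter, and the squamous difference of 3.23 was 1.89 without replicate number 1. With 1 replicate number left out in both fluids (4 libraries each) every one of these 5 differences kept its sign. At that size a list could pass only where the scores of the 2 fluids did not overlap at all. A lost pass there therefore says little about the size of a difference. Passes ended for distal nephron genes without 2, 7 or 8 (2.29, 2.00 and 1.92) and squamous genes without 1, 2, 7 or 8 (1.89, 3.63, 2.78 and 3.83). They ended for hepatocyte genes without 2, 3 or 8 (-0.58, -0.53 and -0.68), ribosomal genes without 1, 2 or 3 (-0.75, -1.11 and -0.97) and mitochondrial genes without 3 (-3.07).

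In AKI the same fluids differed over 34 libraries each, kidney and urothelial genes standing higher in urine and red cell genes higher in plasma. AQP2 (ENSG00000167580.8, chr12:49950741-49958881), the water channel of the collecting duct, had 10160 counts in urine and 2 in plasma (184 ± 189 against 0.100 ± 0.585 CPM), 3143-fold (95% counting interval 869.8 to 25960) more. UPK1A (ENSG00000105668.7, chr19:35666516-35678483), a membrane plaque protein of the bladder lining, had 4444 counts in urine and 2 in plasma (98.5 ± 67.9 against 0.0711 ± 0.314 CPM), 1375-fold (95% counting interval 380.3 to 11360) more. HEMGN (ENSG00000136929.13, chr9:97926791-97944856), a nuclear protein of red cell precursors, was lower in urine by a log2 difference of -10.09 ± 0.41 (0.545 ± 1.85 against 631 ± 427 CPM). HBB (ENSG00000244734.4, chr11:5225464-5229395), beta globin, differed by -10.35 ± 0.77 (9.76 ± 39.3 against 11640 ± 16140 CPM).

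The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment passed 7952 of 10686 genes, 4403 higher in urine and 3549 lower (6995 and 1978 with total-count scaling). Adjusted p by edgeR quasi-likelihood and Benjamini-Hochberg was 6.89e-30 for AQP2, 7.55e-31 for UPK1A, 9.53e-34 for HEMGN and 4.62e-20 for HBB. All 34 urine libraries lay on the stated side of the plasma median for these 4 genes. The urothelial sorting nexin SNX31 was 3397-fold (95% counting interval 609.5 to 134200) higher in urine by its counts. The lactate carrier SLC5A12 of the proximal tubule was 503-fold (95% counting interval 172 to 2439) higher, the epithelial factor SPDEF 5028-fold (95% counting interval 902 to 198600), and the kallikreins KLK4 and KLK3 6400-fold (95% counting interval 1772 to 52850) and 2697-fold (95% counting interval 923 to 13080). MLPH was 9.06 ± 0.43 log2 units higher and cornulin, CRNN, 9.13 ± 1.07 higher. Among genes lower in urine were ALAS2 of heme synthesis (-10.25 ± 0.49), carbonic anhydrase CA1 (-10.16 ± 0.52), HBA1 (-10.54 ± 0.53) and HBA2 (-9.70 ± 0.56). The mitochondrial transfer RNA MT-TR was 3538-fold (95% counting interval 634 to 139800) higher in plasma.

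All 23 list scores differed between the fluids in AKI by permutation test, 20 of them at the Benjamini-Hochberg adjusted p of 1.15e-05 that was the smallest the permutations could give. Lower in urine were platelet genes (0.67 ± 0.85 against 7.20 ± 1.43, 14 of 14 passing), erythroid (0.55 ± 0.31 against 6.999 ± 1.35, 14 of 14) and cytotoxic lymphocyte genes (0.26 ± 0.27 against 4.46 ± 0.62, 7 of 7). Also lower were granulocyte precursor (0.37 ± 0.43 against 4.51 ± 1.53, 11 of 11), monocyte (1.17 ± 0.95 against 5.20 ± 0.64, 11 of 11) and T cell genes (0.23 ± 0.32 against 4.13 ± 0.60, 9 of 9). B cell (0.14 ± 0.17 against 3.52 ± 0.92, 5 of 5), endothelial (0.59 ± 0.35 against 4.34 ± 0.69, 7 of 7), proliferation (1.98 ± 0.92 against 4.57 ± 1.08, 10 of 10) and mitochondrial protein genes (6.30 ± 1.74 against 11.48 ± 0.87, 13 of 13) were lower in all 34 urine libraries. The neutrophil score was lower in 31 of 34 libraries (2.35 ± 2.16 against 5.96 ± 0.67, 9 of 13 passing, 8 when adjusted over the list alone). Type I interferon genes were lower in 29 of 34 (3.57 ± 1.08 against 5.16 ± 0.85) and hepatocyte genes in 32 of 34 (0.65 ± 0.47 against 1.93 ± 1.33). Passing genes, here and in the next paragraph, are counted among those that met the expression filter, such as 5 of the 13 B cell genes. A gene nearly absent from 1 fluid met that filter only through the other, so these counts add little to the scores.

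Higher in AKI urine were urothelial genes (5.37 ± 0.97 against 0.97 ± 0.33, 11 of 11 passing), collecting duct (4.00 ± 0.74 against 0.36 ± 0.23, 8 of 8) and distal nephron genes (4.18 ± 0.88 against 0.79 ± 0.35, 9 of 10). Proximal tubule (3.91 ± 1.12 against 0.66 ± 0.29, 8 of 8), squamous (3.25 ± 1.94 against 0.82 ± 0.62, 9 of 9) and tubular injury genes (5.54 ± 0.61 against 3.42 ± 0.52, 7 of 11, with 2 passing as lower) were higher too. The p53 target score was higher in 33 of 34 libraries (4.72 ± 0.45 against 3.84 ± 0.31, 8 of 14 passing as higher and 1 as lower). GDF15, a stress hormone induced by p53, was 4.22 ± 0.52 higher (35.8 ± 70.0 against 1.99 ± 6.79 CPM), and KRT18, like KRT8 a keratin of simple epithelium, 6.39 ± 0.28 higher (905 ± 267 against 11.5 ± 16.6 CPM). The sodium and chloride carrier SLC12A1 (ENSG00000074803.20, chr15:48178438-48304078) was 6.44 ± 0.37 higher in urine, and myeloperoxidase, MPO, was lower (-8.08 ± 0.38). The 3 scores above the smallest p were interferon gamma (-1.28, permutation adjusted p = 3.29e-05), ribosomal protein (-0.42, adjusted p = 0.000136) and podocyte (0.45, adjusted p = 0.000660). The podocyte difference changed sign with summed counts and the ribosomal one with total-count scaling, and extraction kits differed here too. HBA1 and HBA2 are nearly identical, so their reads cannot be placed with certainty.

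**Figure D1:**
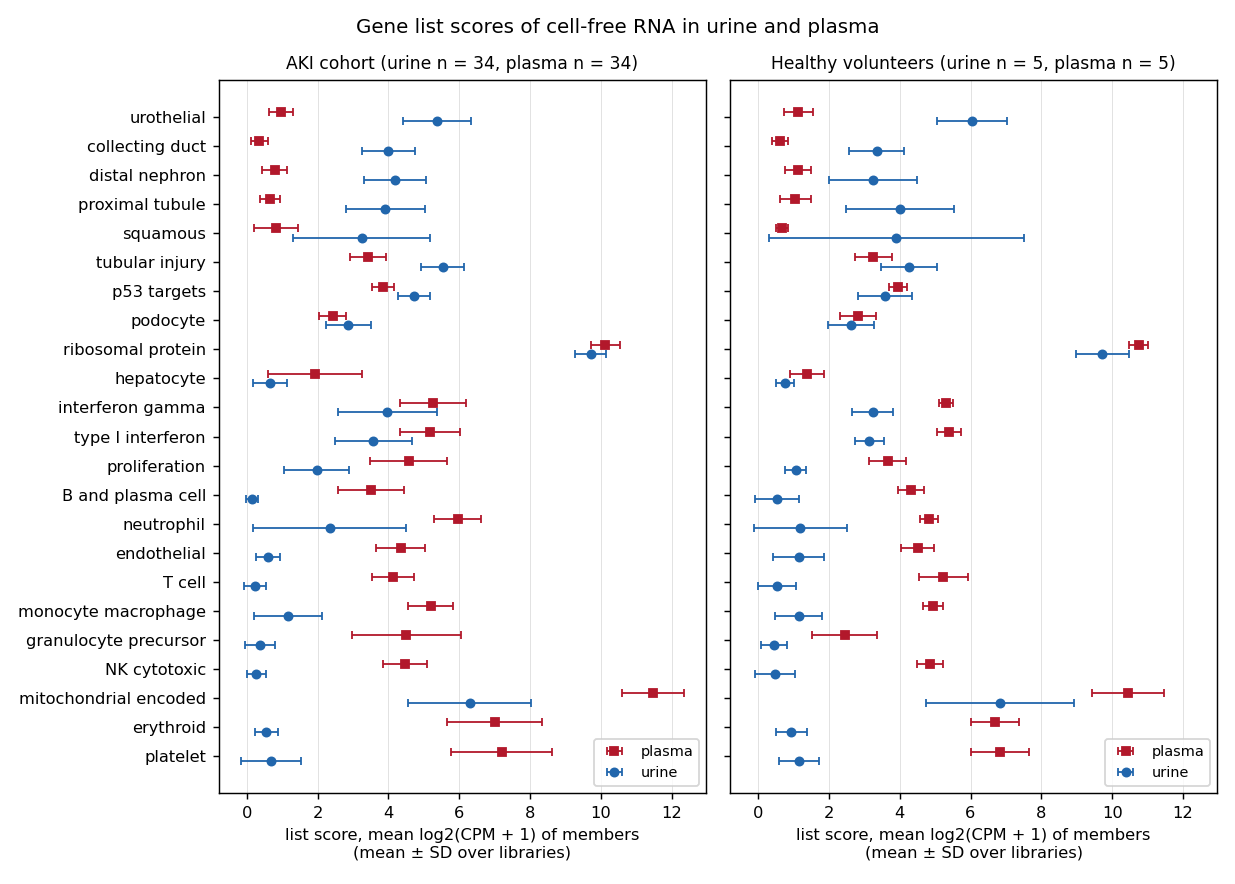
List scores of plasma and urine libraries in healthy volunteers (5 and 5) and in AKI (34 and 34), with the erythroid score at 0.55 ± 0.31 against 6.999 ± 1.35 in AKI urine against plasma.

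HSCT plasma was labelled with 7 times, written as in the labels, PR (13 libraries), D0 (13), E (15), 1M (13), 2M (15), 3M (15) and 6M (13). Across these times 3393 of 10313 genes changed by the edgeR quasi-likelihood test of any difference with Benjamini-Hochberg adjustment. C16orf87 (ENSG00000155330.10, chr16:46796607-46831411), a protein of little-known function, had an adjusted p of 3.11e-11 in that edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and MDM2 (ENSG00000135679.26, chr12:68808176-68850686), the ligase that degrades p53, 2.13e-10. FAS (ENSG00000026103.22, chr10:88990582-89015785), a death receptor induced by p53, and VCAN (ENSG00000038427.16, chr5:83471465-83582303), a matrix proteoglycan of monocytes, had Benjamini-Hochberg adjusted edgeR quasi-likelihood p of 9.16e-10 and 1.59e-08.

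Most genes of the myeloid and lymphoid lists changed over time, with 14 of 15 measured neutrophil genes passing (14 when adjusted over the list alone), 13 of 13 granulocyte precursor genes (13) and 9 of 13 monocyte genes (11). Passing too were 13 of 14 T cell genes (14 when adjusted over the list alone), 9 of 10 cytotoxic lymphocyte genes (9), 7 of 8 B cell genes (7), 10 of 12 proliferation genes (11), 13 of 13 mitochondrial genes and 21 of 21 ribosomal protein genes. Of other lists 5 of 11 p53 targets passed (5 when adjusted over the list alone), 4 of 8 interferon gamma genes (7), 6 of 8 hepatocyte genes (6), 3 of 15 erythroid genes (1) and 3 of 14 platelet genes (3). Of endothelial genes 1 of 11 passed, of type I interferon genes 1 of 17, of tubular injury genes 3 of 8, of distal nephron genes 2 of 2, of urothelial genes 2 of 2 and of collecting duct genes 1 of 1. No podocyte (0 of 4), proximal tubule (0 of 1) or squamous gene (0 of 1) passed. Besides C16orf87, MDM2 and VCAN, the 16 genes of smallest adjusted p among those with a mean of at least 20 CPM were EXOC6B of vesicle docking, MZT1 of spindle assembly, ARL6IP1, LBR of the nuclear envelope, the hexokinase HK3, the splicing factor MBNL2, SH3KBP1, the kinase MATK, TTC27, RPS27L, CDK8, GRK2 and SEPTIN9.

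From PR to D0 plasma gained RNA of p53 targets and mature neutrophils and lost RNA of T cells (13 libraries at each time). FAS rose by 2.51 ± 0.51 log2 units (55.6 ± 147 against 9.99 ± 11.8 CPM) and MDM2 by 0.88 ± 0.17 (225 ± 106 against 122 ± 50.2 CPM), both induced by p53 after DNA damage. The D0 spread of FAS exceeded its mean, so the size of its rise may rest on few libraries. FCGR3B, an antibody receptor of neutrophils, rose by 2.23 ± 0.45 (96.7 ± 101 against 21.4 ± 24.3 CPM). TCF7 (ENSG00000081059.20, chr5:134114711-134151865), a transcription factor of T cells, changed by -2.56 ± 0.50 (7.45 ± 8.76 against 45.9 ± 28.4 CPM), and IRF8 (ENSG00000140968.11, chr16:85898803-85922609), a factor of monocyte and B cell lines, by -2.42 ± 0.35 (15.7 ± 8.72 against 84.8 ± 84.0 CPM).

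The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment passed 1510 genes between D0 and PR, 562 up and 948 down. With total-count scaling 106 rose and 2568 fell, and a fit of only these 2 groups passed 556. Adjusted p by edgeR quasi-likelihood and Benjamini-Hochberg was 0.000337 for FAS, 0.000129 for MDM2, 0.000290 for FCGR3B, 0.000209 for TCF7 and 4.88e-06 for IRF8. All 13 D0 libraries lay under the PR median for TCF7 and IRF8, and 12 lay over it for FCGR3B. Also risen were G0S2, a brake on fat breakdown (2.81 ± 0.56), CLEC4E, a pattern receptor of myeloid cells (2.62 ± 0.69), carbonic anhydrase CA3 (2.30 ± 0.69), the formyl peptide receptor FPR1 (2.23 ± 0.46) and C16orf87 (2.11 ± 0.41). Also fallen were the T cell factors TBX21 (-2.54 ± 0.62) and BCL11B (-2.53 ± 0.57), the kinase LCK (-2.39 ± 0.55), IKZF3 (-2.11 ± 0.51) and CD24 of B cells (-2.05 ± 0.60). The antisense RNA LINC02569 rose by 2.91 ± 0.79, which reads of the opposite strand could mimic.

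The p53 target score rose from PR to D0 (4.55 ± 0.56 against 3.51 ± 0.56, difference 1.04, permutation adjusted p = 0.00104) in 13 of 13 libraries, with 5 of 11 measured genes passing. The T cell score fell (1.82 ± 0.80 against 3.12 ± 0.95, difference -1.30, permutation adjusted p = 0.00472) with 8 of 14 genes passing (10 when adjusted over the list alone). The cytotoxic lymphocyte score fell too (2.65 ± 0.65 against 3.74 ± 0.63, permutation adjusted p = 0.00245), with 4 of 10 genes passing (7 when adjusted over the list alone). The neutrophil score rose (5.54 ± 1.01 against 4.59 ± 0.62, permutation adjusted p = 0.0271) with 9 of 15 genes passing. So did the proliferation score (5.71 ± 0.94 against 4.58 ± 1.00, permutation adjusted p = 0.0247) with 4 of 12 (7 when adjusted over the list alone). Mitochondrial protein genes rose (11.58 ± 1.41 against 10.29 ± 0.93, 13 of 13 passing, permutation adjusted p = 0.0271) and ribosomal protein genes fell (7.87 ± 0.51 against 9.04 ± 0.62, 21 of 21 passing, permutation adjusted p = 0.00104). Tubular injury (0.50, permutation adjusted p = 0.0466, 1 of 8 measured genes passing) and collecting duct scores (0.42, permutation adjusted p = 0.0247) rose, the latter with AQP3 as the only measured gene (2.26 ± 0.48). With total-count scaling the neutrophil, proliferation, p53, mitochondrial, tubular injury and collecting duct scores no longer passed. The mitochondrial ribosomal RNA share was 18.6 ± 8.44% at D0 against 10.0 ± 6.73% at PR. Summed counts gave the neutrophil and cytotoxic scores the other sign, and with libraries of at least 1000000 counts (6 and 6) no list passed. The differences at that depth were 0.94 for neutrophil, -1.21 for T cell, -1.03 for cytotoxic lymphocyte, 2.03 for mitochondrial, -1.44 for ribosomal and 0.58 for tubular injury genes, and smaller for p53 (0.64), proliferation (0.32) and collecting duct genes (0.11).

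From D0 to E plasma gained RNA of immature granulocytes and of monocytes and lost RNA of p53 targets (15 and 13 libraries). MPO (ENSG00000005381.8, chr17:58269856-58280935), the peroxidase of neutrophil granules, rose by 3.89 ± 0.71 (231 ± 294 against 14.2 ± 15.99 CPM). RETN (ENSG00000104918.8, chr19:7669044-7670454), resistin of myeloid cells, rose by 4.67 ± 0.71 (39.6 ± 37.3 against 1.87 ± 2.502 CPM) and VCAN by 2.66 ± 0.37 (182 ± 211 against 28.3 ± 12.8 CPM). S100A8 (ENSG00000143546.10, chr1:153390032-153391188), a calcium-binding alarm protein of neutrophils and monocytes, rose by 2.79 ± 0.48 (4506 ± 2996 against 654 ± 543 CPM). MDM2 changed by -1.24 ± 0.16 (95.4 ± 26.6 against 225 ± 106 CPM) and FAS by -2.74 ± 0.48 (8.78 ± 9.25 against 55.6 ± 147 CPM). The size of the FAS fall may rest on few D0 libraries, given their spread.

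By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 4048 genes passed between E and D0, 2128 up and 1920 down (4173 and 675 with total-count scaling). Adjusted p by edgeR quasi-likelihood and Benjamini-Hochberg was 2.55e-07 for RETN, 8.98e-06 for MPO, 2.71e-08 for VCAN, 2.29e-06 for S100A8 and 5.25e-09 for MDM2. RETN was over the D0 median in all 15 E libraries and MPO in 14. Also risen were the collagenase MMP8 by 4.28 ± 0.72, the protease PRTN3 by 4.09 ± 0.82, MS4A3 by 3.86 ± 0.68, SERPINB10 by 4.32 ± 0.80, CD177 by 3.98 ± 0.88 and the defensin DEFA3, nearly identical to DEFA1, by 4.58 ± 0.87. CA3 (-3.81 ± 0.71), the zinc finger gene ZNF438 (-3.17 ± 0.52), the chemokine CXCL3 (-3.12 ± 0.48) and C16orf87 (-3.05 ± 0.40) fell. Falls of the processed pseudogene TMSB4XP6 (-3.12 ± 0.44), the lincRNA SAMD4A-AS1 (-3.001 ± 0.58) and the antisense MEF2C-AS1 (-2.69 ± 0.40) are uncertain, since such genes share reads with others.

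The granulocyte precursor score rose from D0 to E (4.84 ± 1.82 against 2.17 ± 0.93, difference 2.66) in 14 of 15 libraries with 13 of 13 genes passing, and the monocyte score rose (4.86 ± 0.69 against 3.76 ± 0.52) with 8 of 13. The p53 target score fell (3.75 ± 0.39 against 4.55 ± 0.56) in 15 of 15 libraries with 6 of 11 genes passing (7 when adjusted over the list alone), and the ribosomal score rose (8.98 ± 0.45 against 7.87 ± 0.51, 21 of 21). These 4 lists had a Benjamini-Hochberg adjusted permutation p of 0.000460, and mitochondrial genes, which fell (10.07 ± 1.45 against 11.58 ± 1.41, 13 of 13 passing), had 0.0400 by permutation. The neutrophil score did not pass (0.28, permutation adjusted p = 0.587), with 4 genes up and 5 down, but did with summed CPM (2.10, permutation adjusted p = 0.000115). Total-count scaling ended the passes of the p53 and mitochondrial scores, and a depth of at least 1000000 counts (8 and 6 libraries) those of the granulocyte precursor (2.92), monocyte (1.24) and p53 scores (-0.63). The D0 libraries enter both this comparison and the one with PR.

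From PR to E scores of neutrophil, monocyte and granulocyte precursor genes rose (13 and 15 libraries). MPO rose by 3.14 ± 0.67 (231 ± 294 against 24.96 ± 22.97 CPM), and S100A12 (ENSG00000163221.9, chr1:153373706-153375649), an alarm protein of neutrophils, by 3.12 ± 0.56 (417 ± 358 against 47.7 ± 32.9 CPM). LCK (ENSG00000182866.17, chr1:32251239-32286165), the kinase that starts T cell receptor signals, changed by -1.80 ± 0.47 (11.6 ± 8.82 against 41.9 ± 36.7 CPM), and PAX5 (ENSG00000196092.14, chr9:36833275-37034185), the master factor of B cells, by -2.17 ± 0.62 (4.10 ± 3.36 against 21.0 ± 19.3 CPM).

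By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 718 genes passed between E and PR, 400 up and 318 down (177 and 89 with total-count scaling, 391 genes in a fit of only these 2 groups). Adjusted p by edgeR quasi-likelihood and Benjamini-Hochberg was 0.000192 for S100A12, 0.00203 for MPO, 0.0114 for LCK and 0.0206 for PAX5. The alkaline phosphatase ALPL of neutrophils (2.51 ± 0.54), elastase ELANE (2.57 ± 0.69), PRTN3 (2.88 ± 0.72), RETN (2.73 ± 0.56), MMP8 (2.65 ± 0.61) and DEFA3 (2.94 ± 0.77) rose. Falling were IGFBP2, a binder of growth factors (-2.93 ± 0.75), the clock gene PER3 (-1.94 ± 0.41), BCL11B (-2.02 ± 0.48) and the protease inhibitor CST7 (-3.40 ± 0.95). The pseudogenes DDX11L9 (-2.22 ± 0.71) and TMSB4XP6 (-1.99 ± 0.44) and the RNA SAMD4A-AS1 (-1.86 ± 0.58) also fell.

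Neutrophil (5.82 ± 0.65 against 4.59 ± 0.62, 8 of 15 genes passing and 9 up and 1 down when adjusted over the list alone) and monocyte scores (4.86 ± 0.69 against 3.79 ± 0.81, 8 of 13 and 11) rose from PR to E. So did the granulocyte precursor score (4.84 ± 1.82 against 3.08 ± 1.19, 11 of 13 and 12). The B cell score fell (1.21 ± 0.51 against 1.97 ± 0.64, 3 of 8 and 6). Permutation tests adjusted by Benjamini-Hochberg gave p of 0.00115, 0.00529, 0.0357 and 0.0107 for these 4 lists, and 0.0520 for T cells (-0.96), which did not pass. Total-count scaling ended the granulocyte precursor and B cell passes, and with libraries of at least 1000000 counts (8 and 6) the neutrophil score passed (1.19) and the monocyte (1.10), granulocyte precursor (1.18) and B cell scores (-0.47) did not. CST7 lay under its PR median in only 6 of 15 E libraries and changed sign under DESeq2.

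Between 6M and PR (13 libraries each) no gene passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, against 803 genes at unadjusted p under 0.05 and 0 passing genes by DESeq2. No list score passed the permutation tests, the largest difference being the cytotoxic lymphocyte score (4.41 ± 0.87 against 3.74 ± 0.63, adjusted p = 0.823). CD22 (ENSG00000012124.17, chr19:35319261-35347355), an inhibitory receptor of B cells, differed by 1.74 ± 0.54 (29.9 ± 26.4 against 9.24 ± 8.92 CPM) without passing. Simulated changes of 2-fold were found in 60% of changed genes with at least 20 CPM and of 4-fold in 97% at this size.

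**Figure D2:**
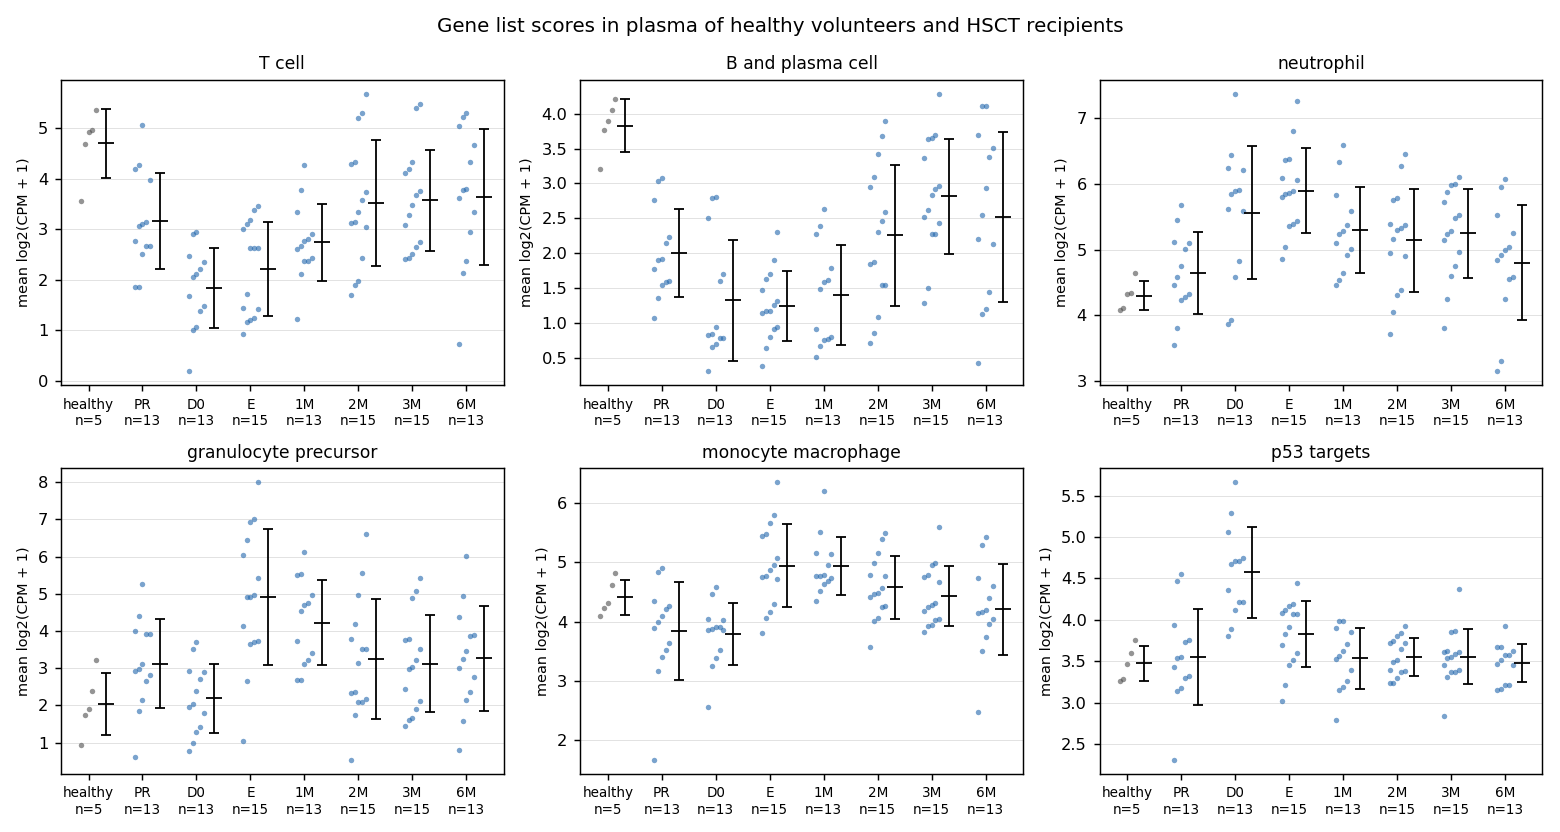
List scores of healthy plasma libraries and of HSCT plasma libraries over the 7 labelled times. Scaled over all plasma libraries, the granulocyte precursor score stood at 4.91 ± 1.83 against 2.19 ± 0.935 at E and D0.

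Within AKI urine, TP2 (19 libraries) and TP1 (15) did not differ in any gene by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 9916 genes, with 303 at unadjusted p under 0.05 and 2 passing by DESeq2. SPP1, osteopontin of injured tubule, differed by -1.14 ± 0.40 (107 ± 84.8 against 241 ± 188 CPM), and IFI44L, induced by type I interferon, by -2.33 ± 0.59 (11.5 ± 11.5 against 60.9 ± 122 CPM), neither passing. The tubular injury score was 5.61 ± 0.57 against 6.17 ± 0.53 (difference -0.56, permutation adjusted p = 0.154). The interferon gamma score differed by -1.14 (permutation adjusted p = 0.267), with 3 genes lower when adjusted over the list alone. None of the 23 list scores passed. Simulated changes of 2-fold were found in 70% of changed genes with at least 20 CPM and of 4-fold in 96%.

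Within AKI plasma, TP2 (19 libraries) and TP1 (15) did not differ in any gene by edgeR quasi-likelihood with Benjamini-Hochberg adjustment over 6857 genes, with 294 at unadjusted p under 0.05 and 0 by DESeq2. S100A12, the alarm protein of neutrophils, differed by -1.19 ± 0.38 (70.3 ± 38.9 against 162 ± 183 CPM) and CD247, a chain of the T cell receptor, by 0.94 ± 0.34 (44.2 ± 33.1 against 21.9 ± 14.3 CPM), neither passing. The neutrophil score differed by -0.25 (permutation adjusted p = 0.660), and no list passed. Simulated changes of 2-fold were found in 75% of changed genes with at least 20 CPM and of 4-fold in 82%.

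The change from TP1 to TP2 did not differ between urine and plasma in any of 10686 genes by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 485 having unadjusted p under 0.05 (DESeq2 was not run for this model). The difference of changes was -4.36 ± 1.11 for SPP1, -2.73 ± 0.73 for IFI44L and -1.82 ± 0.58 for the p53 target PHLDA3, none passing. List scores differed by -0.62 for tubular injury, -0.96 for interferon gamma and -0.32 for p53 targets, each with a permutation adjusted p of 0.515. Simulated changes of 2-fold were found in 32% of changed genes with at least 20 CPM and of 4-fold in 86%, so small differences would have been missed.

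Urine in AKI (34 libraries) had higher scores of tubular injury and p53 genes than healthy urine (5). Tubular injury genes scored 5.85 ± 0.61 against 4.40 ± 0.82, a rise of 1.46 in 34 of 34 libraries, and p53 targets, induced by DNA damage, 5.04 ± 0.44 against 3.76 ± 0.81, a rise of 1.29 in 33 of 34 libraries. Exact permutation tests with Benjamini-Hochberg adjustment over the 23 lists gave p of 0.00130 and 0.00104. No single member passed among all genes, and 3 tubular injury genes and 5 p53 targets rose when adjusted over the list alone. TNFRSF10B, a death receptor, differed by 1.91 ± 0.50 (62.5 ± 48.2 against 12.8 ± 9.87 CPM), PROM1 of regrowing tubule by 1.34 ± 0.39 (48.0 ± 22.3 against 18.4 ± 5.25 CPM) and SPP1 by 2.61 ± 0.77 (166 ± 152 against 23.9 ± 35.8 CPM).

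By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 22 of 12184 genes passed between AKI and healthy urine, 4 up and 18 down (1206 at unadjusted p under 0.05). DESeq2 passed 105, 84 up and 21 down, of which 10 were among the 22. RPLP0P6 (ENSG00000213553.4, chr2:38481851-38482804, a processed pseudogene of a ribosomal stalk protein) rose by 3.02 ± 0.51 (73.9 ± 36.9 against 6.45 ± 6.96 CPM) in all 34 libraries, while the pseudogene RPL13AP5 rose by 1.72 ± 0.35 and CENPB, which binds centromeres, by 1.15 ± 0.26. FLG (ENSG00000143631.11, chr1:152302175-152325203), filaggrin of the horny layer of skin, changed by -5.67 ± 0.99 (18.6 ± 46.1 against 754 ± 1652 CPM). The edgeR quasi-likelihood p with Benjamini-Hochberg adjustment was 0.00250 for FLG, 0.00201 for RPLP0P6 and 0.0480 for CENPB. Also lower were SPRR2E (-5.57 ± 1.05), ALOX12 (-5.39 ± 1.03), ECM1 (-5.29 ± 1.01), CRCT1 (-4.96 ± 1.05), the protease inhibitor A2ML1 (-3.71 ± 0.78), the secreted CRISP3 (-4.48 ± 0.76) and the sulfhydryl oxidase QSOX1 (-3.21 ± 0.59). The neutrophil receptor FPR1 (135-fold (95% counting interval 24.1 to 5324)), MMP25 (at least 15.95-fold) and the chemokine CXCL10 (27.6-fold (95% counting interval 9.39 to 134)) had more counts in AKI urine without passing. The squamous score did not pass (-0.56, exact permutation adjusted p = 0.780), though 11 of 13 measured squamous genes fell when adjusted over the list alone, nor did the distal nephron (1.08) or proliferation score (1.04), both at an exact permutation adjusted p of 0.0887.

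Leaving out healthy urine replicate 1 left 1 of the 22 genes. Summed CPM gave the tubular injury score the other sign (-0.19) and ended the p53 pass (0.66, exact permutation adjusted p = 0.0693). At 1000000 counts or more the differences were 1.16 for tubular injury and 0.76 for p53 genes, neither passing, but 15 and 2 libraries are too few for 2 of 23 lists to pass even at the smallest p possible. Olfactory receptor genes differed too, with a median of 182.3 CPM in healthy urine against 17.9 and 19.7 at TP1 and TP2. AKI urine libraries carried a read length in their names that healthy ones lacked, so disease cannot be told from batch, and pseudogenes share reads with their parents.

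**Figure D3:**
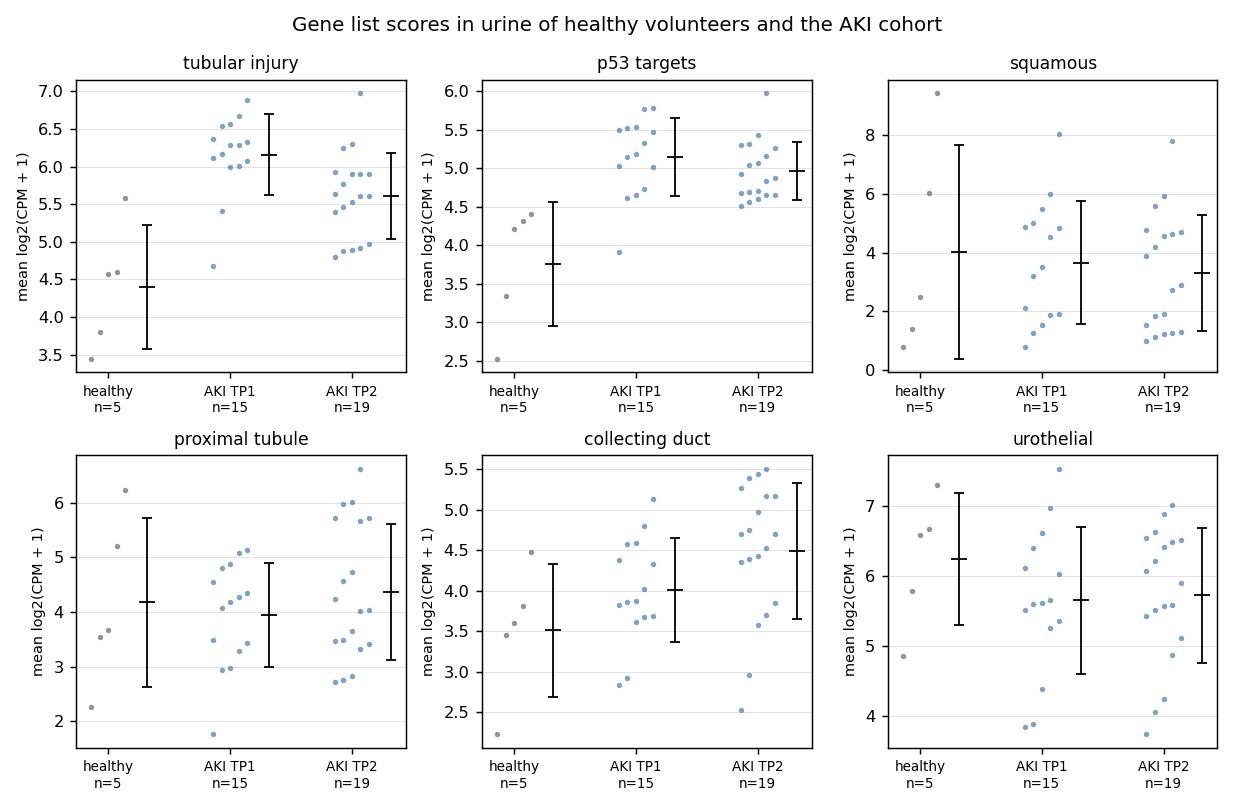
Scores in healthy and AKI urine libraries, with tubular injury genes at 5.85 ± 0.61 against 4.40 ± 0.82 and p53 targets at 5.04 ± 0.44 against 3.76 ± 0.81 in AKI against healthy.

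Plasma in AKI (34 libraries) carried more neutrophil and granulocyte precursor RNA and less T cell RNA than healthy plasma (5). S100A8, the alarm protein of neutrophils, rose by 3.18 ± 0.77 (2764 ± 3069 against 299.9 ± 96.96 CPM) and LCN2 (ENSG00000148346.12, chr9:128149071-128153455), an iron carrier released by neutrophils and injured tubule, by 2.49 ± 0.62 (117 ± 102 against 20.9 ± 6.66 CPM). TCF7, the T cell factor, changed by -1.66 ± 0.40 (87.8 ± 57.4 against 272 ± 132 CPM) and LEF1, its close relative, by -1.81 ± 0.34 (35.1 ± 20.7 against 120.4 ± 54.6 CPM). The neutrophil score rose (5.67 ± 0.64 against 4.40 ± 0.25, difference 1.28) in 34 of 34 libraries and the T cell score fell (3.87 ± 0.59 against 4.79 ± 0.67, difference -0.92) in 32 of 34.

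By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 42 of 9473 genes passed between AKI and healthy plasma, 29 up and 13 down (1161 at unadjusted p under 0.05). DESeq2 passed 273, 225 up and 48 down. The direction depended on the setting, with 13 up and 29 down by total-count scaling and 5 up and 16 down at 1000000 counts or more. It was 9 up and 9 down without healthy plasma replicate 1, 4 and 8 without 2, 5 and 9 without 3, 14 and 15 without 7 and 6 and 8 without 8. Adjusted p by edgeR quasi-likelihood and Benjamini-Hochberg was 0.0490 for S100A8, 0.0490 for LCN2, 0.0490 for TCF7 and 0.00298 for LEF1. The lipid exporter ABCG1 (4.95 ± 1.11) and the zinc finger gene ZNF302 (3.76 ± 0.92) rose, and the tubulin regulator TBCEL (-1.49 ± 0.35) and BCL11B (-1.24 ± 0.31) fell. Rises of the spliceosomal RNAs RNU5B-1 (3.64 ± 0.79), RNU5A-1 (3.33 ± 0.82) and RNVU1-28 (3.23 ± 0.66) and of RALY-AS1 (4.64 ± 1.07) are uncertain because such genes have many copies or share reads with their neighbours. The processed pseudogenes RPL7P9 (-2.95 ± 0.26), EEF1A1P5 (-2.52 ± 0.26), RPS3AP26 (-1.52 ± 0.28) and RPS3AP6 (-1.47 ± 0.29) fell.

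Exact permutation tests with Benjamini-Hochberg adjustment passed 4 lists, neutrophil (0.00112), granulocyte precursor (4.24 ± 1.5 against 2.12 ± 0.85, 0.0268), T cell (0.0268) and mitochondrial genes (11.17 ± 0.83 against 9.98 ± 1.00, 0.0333). Among all genes 2 of 14 neutrophil, 1 of 13 granulocyte precursor, 0 of 12 T cell and 0 of 13 mitochondrial list genes passed. When adjusted over the list alone 13 neutrophil, 13 granulocyte precursor and 10 mitochondrial genes rose and 7 T cell genes fell. PRTN3, a protease of granules, rose by 3.45 ± 0.75 (15.01 ± 13.5 against 1.57 ± 1.59 CPM). Total-count scaling ended the granulocyte precursor and mitochondrial passes, and leaving out single healthy libraries ended those of granulocyte precursor (1.83 to 2.40, without replicate 1, 2 or 3), T cell (-1.17 to -0.75, without 2, 3 or 8) and mitochondrial genes (0.93 to 1.59, without 2, 3, 7 or 8). At 1000000 counts or more (5 and 4 libraries) none of the 4 lists passed, though their differences were larger than over all libraries (neutrophil 1.68, granulocyte precursor 2.81, T cell -1.33, mitochondrial 1.57). Libraries differed in quality as well, with RN7SL genes at 3.32 ± 0.70% of counts in AKI plasma against 1.33 ± 0.15% in healthy plasma, 15502 ± 1835 genes detected against 21968 ± 3766, and median totals of 640130 and 1421525 counts. Trimming marks in AKI plasma library names were absent from healthy ones, so disease cannot be told from batch.

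HSCT plasma at PR (13 libraries) carried less B and T cell RNA and more platelet and red cell RNA than healthy plasma (5). CD22, the inhibitory receptor of B cells, changed by -2.67 ± 0.48 (10.2 ± 9.74 against 65.7 ± 23.6 CPM), PAX5 by -2.75 ± 0.52 (23.02 ± 20.9 against 134 ± 53.9 CPM) and TCF7 by -2.39 ± 0.47 (50.1 ± 30.8 against 254 ± 124 CPM). GP1BA (ENSG00000185245.8, chr17:4932297-4935030), the platelet receptor for von Willebrand factor, rose by 2.55 ± 0.59 (333 ± 236 against 57.0 ± 38.0 CPM). LCN2 rose by 3.42 ± 0.57 (209 ± 158 against 19.6 ± 6.71 CPM).

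The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment passed 1814 of 9970 genes between PR and healthy plasma, 1259 up and 555 down. Total-count scaling turned this to 535 up and 1095 down, and with 1 healthy library left out 315 to 1346 genes passed (548, 315, 1096 and 522 without plasma replicates 2, 3, 7 and 8). Adjusted p by edgeR quasi-likelihood and Benjamini-Hochberg was 0.00539 for CD22, 0.00626 for PAX5, 0.00631 for TCF7, 0.0108 for GP1BA and 0.00500 for LCN2. All 13 PR libraries lay under the healthy median for CD22, PAX5 and TCF7. The BMP antagonist GREM1 (5.02 ± 1.09), heparanase HPSE (4.85 ± 0.89), the platelet chemokine PF4V1 (5.03 ± 1.31), the kinase BRSK1 (7.97 ± 2.12) and CACNG2 (4.58 ± 0.81) rose. IGFBP2 (4.43 ± 1.32), the mitochondrial transfer RNA MT-TS2 (5.23 ± 1.12) and the pseudogene-like RNA RN7SL555P (4.85 ± 0.85) rose too. The IgM receptor FCMR (-2.58 ± 0.52), BACH2 (-2.43 ± 0.41) and TCL1A (-2.25 ± 0.68) of B cells, WDFY4 of antigen presentation (-2.11 ± 0.31) and LEF1 (-2.41 ± 0.55) fell.

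B cell (2.05 ± 0.65 against 3.84 ± 0.35), T cell (3.22 ± 0.96 against 4.70 ± 0.65) and ribosomal protein scores (9.18 ± 0.60 against 10.18 ± 0.26) fell at PR, with exact permutation adjusted p of 0.00268, 0.0349 and 0.0224 after Benjamini-Hochberg adjustment. Erythroid (7.93 ± 0.78 against 6.15 ± 0.68), platelet (8.60 ± 1.60 against 6.32 ± 0.82), proliferation (4.70 ± 1.02 against 3.20 ± 0.51) and tubular injury scores (3.65 ± 0.54 against 2.87 ± 0.48) rose, with exact permutation adjusted p of 0.00403, 0.0380, 0.0349 and 0.0414. Passing members numbered 5 of 8 for B cells (7 when adjusted over the list alone), 4 of 14 for T cells (6) and 11 of 21 for ribosomal proteins (18). They numbered 10 of 15 for erythroid (13), 13 of 14 for platelet (14), 9 of 12 for proliferation (12) and 4 of 6 for tubular injury genes (4). Proximal tubule and distal nephron scores did not rise, at -0.31 to -0.063 and -0.30 to -0.12 with 1 healthy library left out. Only 0 of 15 and 1 of 13 genes of these lists met the expression filter, the latter at 2.08 without passing. Scores this near the floor cannot tell whether kidney RNA rose. The cell source of the tubular injury genes in plasma was not tested. Leaving out single healthy libraries ended the passes of T cell (-1.75 to -1.32, without replicate 1, 2, 3 or 8), platelet (2.09 to 2.63, without 2, 3, 7 or 8), tubular injury (0.62 to 0.91, without 1, 2, 3 or 8) and proliferation scores (1.34 to 1.64, without 1, 2 or 3), and total-count scaling those of tubular injury and proliferation. At 1000000 counts or more (6 and 4 libraries) none of the 7 passed, with a smaller difference for platelet genes (2.04) and larger ones for B cell (-2.35), T cell (-1.86), erythroid (2.01), proliferation (2.28), ribosomal (-1.14) and tubular injury genes (0.98). PR libraries held 18020 ± 6485 detected genes against 21968 ± 3766 in healthy plasma, median totals of 866784 and 1421525 counts and median olfactory receptor levels of 50.1 and 146.6 CPM. The 5 healthy libraries came from another cohort, so group cannot be told from batch.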

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

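Both tests of the urine pattern in the next paragraph were chosen after the result was seen, and the outlying libraries were found with a ratio test fixed before the data were examined.

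Of the 22 genes that passed between AKI and healthy urine, 18 were lower in AKI, among them FLG, SPRR2E, CRCT1 and A2ML1. Without healthy urine replicate 1 only 1 of the 22 passed, a rising gene, so calls of other rising genes were lost too. That library held 46.7% of the healthy-urine counts of these 18 genes but 1.47% of all healthy-urine counts. Their median there was 1051 CPM of total counts, against 18.1 in the other healthy libraries and 19.1 in AKI urine. The squamous score of replicate 1 was 9.43, against 0.782 to 6.02 in the other 4. The ratio test did not call that score outlying, and AKI urine libraries reached 8.02 (TP1 replicate 13) and 7.80 (TP2 replicate 11). The 18 genes had a median of 82.5 counts in replicate 1 (10 to 661) although that library held 78501 in all. This argues against few counts as the cause only so far as counts of amplified reads stand for molecules. The calls thus rest largely on 1 healthy urine library and are weak evidence of a change in AKI. The genes were picked for standing high in healthy urine. The share of their counts in 1 such library therefore cannot show that squamous RNA is the cause.

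A library stood apart from the other 4 of its healthy group in 10 of 56 measures, where about 5% would be so by chance. Healthy urine replicate 1 did so in 6 of them, with monocyte, T cell, B cell and endothelial scores of 2.40, 1.53, 1.71 and 2.48 (next 1.06, 0.412, 0.360 and 1.07), 7.61% mitochondrial ribosomal RNA (next 0.546%) and 84.8% of counts on protein-coding genes (next 93.6%). It also had 757.6 olfactory receptor CPM, the only library of its group over 500. It held only 78501 counts in all, so those low cell scores may rest on a few reads each. Healthy urine replicate 7 had a cytotoxic lymphocyte score of 1.53 (next 0.456), and healthy urine replicate 3 had 3736892 counts (next 1036263). Among healthy plasma libraries replicate 1 had a platelet score of 7.73 (next 6.19), and replicate 7 had 579732 counts (next 1320145).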

How the results depend on the processing

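The alternatives leaving out mitochondrial and RN7SL genes, libraries with over 500 olfactory receptor CPM, or single healthy libraries for scores, and that with the olfactory receptor share as a covariate, were chosen after the result was seen, and the rest before the data were examined. Of the values of named genes under all alternatives 5296 kept their call, 279 lost it, 58 gained one and 24 changed sign. For list scores these were 1509, 92, 25 and 7, and for counts of passing genes 83 stayed near and 32 moved. The cause was not tested for any changed result unless stated. In 143 cases a named gene had no value under an alternative.

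Without the expression filter 16056 genes passed between AKI fluids, 9079 over time in HSCT plasma, 351 between E and PR, 3 between 6M and PR, 11 in the difference of changes, 214 between AKI and healthy urine and 216 between AKI and healthy plasma, with 28.7% of the last higher in AKI. Fits of only the 2 groups passed 556 genes for D0 against PR and 391 for E against PR. DESeq2 passed 2 for TP2 against TP1 in AKI urine, 105 for AKI against healthy urine (84 up and 21 down, 10 shared with the 22) and 273 for AKI against healthy plasma (225 up and 48 down). Without mitochondrial and RN7SL genes 22 passed for AKI against healthy plasma.

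With only libraries of at least 1000000 counts 198 genes passed for E against PR, 3 for 6M against PR, 21 for AKI against healthy plasma and 573 for PR against healthy plasma. For AKI against healthy urine 0 passed by edgeR quasi-likelihood (524 at unadjusted p under 0.05, 105 by DESeq2 on all libraries). Without libraries of over 500 olfactory receptor CPM 1 and 25 passed for AKI against healthy urine and plasma.

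Total-count scaling passed 2674 genes for D0 against PR and 266 for E against PR. It moved the median log2 difference from -0.0446 to 0.38 between healthy fluids (higher share of passing genes 46.5% to 64.0%), from 0.132 to 0.81 between AKI fluids (55.4% to 78.0%) and from 0.0211 to -0.43 for D0 against PR (37.2% to 3.96%). The median went from 0.0131 to 0.58 for E against D0 (52.6% to 86.1%), from 0.0034 to 0.11 for E against PR (55.7% to 66.5%), from 0.0282 to -0.27 for AKI against healthy plasma (69.0% to 31.0%) and from -0.0163 to -0.47 for PR against healthy plasma (69.4% to 32.8%).

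Leaving out 1 healthy library at a time, 2994 to 4419 genes passed between healthy fluids (1 replicate number left out in both) and 1 to 36 between AKI and healthy urine (1 without urine replicate 1, 36 without replicate 3). Between AKI and healthy plasma 12 to 29 passed (18, 12, 14 and 14 without plasma replicates 1, 2, 3 and 8), and between PR and healthy plasma 315 to 1346 (548, 315, 1096 and 522 without 2, 3, 7 and 8). With the healthy numbers as pairs 3681 genes passed between fluids, 3595 shared with the 4141, and the sign-flip test of list scores could give no p under 0.0625.

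Between healthy fluids summed CPM gave differences of -4.66 for neutrophil and -0.29 for hepatocyte scores, which lost their passes, and -2.58 for podocyte and 2.63 for tubular injury scores, which gained them. A pseudocount of 5 gave 0.94 for tubular injury, now passing, and -0.18 for hepatocyte, lost. Total-count CPM gave 1.27 for tubular injury, now passing, and -0.50 for hepatocyte and -0.63 for ribosomal genes, lost. Leaving out 1 replicate number in both fluids gave 1.83 to 2.53 for distal nephron (lost without 2, 7 or 8), 1.89 to 4.01 for squamous (1, 2, 7 or 8), -0.79 to -0.51 for hepatocyte (2, 3 or 8), -4.06 to -3.07 for mitochondrial (3) and -1.18 to -0.75 for ribosomal scores (1, 2 or 3). In these smaller sets a list could pass only where the scores of the fluids did not overlap at all. With libraries of at least 1000000 counts the smallest p possible was 0.0667 here and 0.1 for TP2 against TP1 in AKI plasma.

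Between AKI fluids the podocyte difference was -2.14 with summed CPM, the other sign, and 0.0548 with a pseudocount of 5, lost. The ribosomal difference was 0.28 with total-count CPM and 0.025 at 1000000 counts or more, both the other sign, and the interferon gamma difference -1.47 at that depth, lost.

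For D0 against PR summed CPM turned the neutrophil (-0.0917) and cytotoxic lymphocyte differences (1.12) and ended the tubular injury pass (0.75). Total-count CPM ended the passes of neutrophil (0.53), collecting duct (0.36), tubular injury (0.21), proliferation (0.72), p53 (0.64) and mitochondrial scores (0.84). At 1000000 counts or more no list passed, with 0.94 for neutrophil, -1.21 for T cell, -1.03 for cytotoxic lymphocyte, 0.11 for collecting duct, 0.58 for tubular injury, 0.32 for proliferation, 0.64 for p53, 2.03 for mitochondrial and -1.44 for ribosomal genes. Without libraries of high olfactory receptor share the B cell score passed (-0.78) and tubular injury did not (0.40).

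For E against D0 summed CPM gave passes to neutrophil (2.10), erythroid (-1.77), platelet (-1.40), distal nephron (-1.14), collecting duct (-1.34), podocyte (-0.77) and tubular injury scores (-0.95), and turned the cytotoxic lymphocyte difference (-1.75). A pseudocount of 5 gave a pass to tubular injury (-0.34). Total-count CPM ended the passes of p53 (-0.31) and mitochondrial scores (-0.95), and a depth of 1000000 those of granulocyte precursor (2.92), monocyte (1.24) and p53 scores (-0.63). IGHM turned to 0.34 at that depth.

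For E against PR summed CPM gave passes to T cell (-1.41), erythroid (-2.19) and urothelial scores (1.11), and a pseudocount of 5 to T cell (-0.64) and urothelial scores (0.14). Total-count CPM ended the passes of granulocyte precursor (1.88) and B cell scores (-0.70), a depth of 1000000 those of granulocyte precursor (1.18), monocyte (1.10) and B cell scores (-0.47), and leaving out libraries of high olfactory receptor share that of granulocyte precursor genes (1.73). CST7 turned to 0.38 with DESeq2.

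For AKI against healthy urine the tubular injury difference was -0.19 with summed CPM, the other sign, and 1.16 at 1000000 counts or more, lost, and the p53 difference 0.66 and 0.76, both lost. The distal nephron difference was 0.61 to 1.47 with 1 healthy library left out, passing without replicate 3. At 1000000 counts or more FLG (3.00), SPRR2E (5.18), ALOX12 (4.09), ECM1 (3.65), CRCT1 (6.58), CRISP3 (3.21), A2ML1 (0.0616) and QSOX1 (1.07) changed sign. Without urine replicate 1, also the only library left out for its olfactory receptor share, 7 of them did so. With 1 healthy library left out their lowest and highest values, without replicates 3 and 1, were -6.08 and 0.25 for FLG, -6.00 and 5.69 for SPRR2E, -5.80 and 0.81 for ALOX12, -5.72 and 2.30 for ECM1, -5.38 and 1.71 for CRCT1, -4.90 and 0.0775 for CRISP3 and -3.61 and 0.12 for QSOX1.

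For AKI against healthy plasma total-count CPM ended the passes of granulocyte precursor (1.87) and mitochondrial scores (0.87), and a depth of 1000000 those of neutrophil (1.68), granulocyte precursor (2.81), T cell (-1.33) and mitochondrial scores (1.57). At that depth so few libraries were left that a pass needed several lists at the smallest p possible. Leaving out 1 healthy library gave 1.83 to 2.40 for granulocyte precursor (lost without plasma replicate 1, 2 or 3), -1.17 to -0.75 for T cell (2, 3 or 8) and 0.93 to 1.59 for mitochondrial scores (2, 3, 7 or 8).

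For PR against healthy plasma summed CPM gave passes to neutrophil (1.18), granulocyte precursor (1.69) and p53 scores (0.75), and total-count CPM to cytotoxic lymphocyte (-0.95) and podocyte scores (-0.73) while ending those of tubular injury (0.45) and proliferation (1.08). A depth of 1000000 ended those of T cell (-1.86), B cell (-2.35), erythroid (2.01), platelet (2.04), tubular injury (0.98), proliferation (2.28) and ribosomal scores (-1.14). So few libraries were left there that a pass needed several lists at the smallest p possible. Leaving out 1 healthy library gave -1.75 to -1.32 for T cell (lost without plasma replicate 1, 2, 3 or 8), 2.09 to 2.63 for platelet (2, 3, 7 or 8), 0.62 to 0.91 for tubular injury (1, 2, 3 or 8), 1.34 to 1.64 for proliferation (1, 2 or 3) and -0.59 to -0.30 for podocyte scores (passing without 8).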

Other observations

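The tests in this part on background and scaling and on pseudogenes were written down before their values were seen, while the scores at 1M, 2M and 3M, the draws of random partner genes and the first 5 split tests (fluid in healthy volunteers and in AKI, any difference over time, D0 against PR, E against D0) were chosen after the main results were seen.

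Monocyte RNA in HSCT plasma was also higher at 1M than at PR, with a score of 4.91 ± 0.44 against 3.79 ± 0.81 (difference 1.12, 13 libraries each, permutation p = 2e-05, 0.00138 after Benjamini-Hochberg adjustment over 69 tests). None of the other scores passed at 1M, 2M or 3M. B cell genes at 3M scored 2.76 ± 0.80 against 1.97 ± 0.64, cytotoxic lymphocyte genes at 2M 4.53 ± 0.66 against 3.74 ± 0.63 and type I interferon genes at 2M 5.44 ± 1.15 against 4.35 ± 0.95, each with a permutation adjusted p of 0.109. Interferon gamma and monocyte scores at 2M differed by 0.73 and 0.71 at the same adjusted p in the permutation test.

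The p53 target score stood 1.04 higher at D0 than at PR in HSCT plasma, where olfactory receptor genes had a median of 76.6 CPM at D0 and 50.1 at PR. With the olfactory receptor share as a covariate the difference was 0.883 (permutation p = 0.00026), which argues against background, so far as that share measures it, as the whole cause. With total-count CPM it was 0.641 (permutation p = 0.0543), and the rule written beforehand counted a p of 0.05 or more toward scaling, but a missed threshold does not show that scaling was the cause. The part of scaling is therefore open, and no biological explanation was tested.

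Processed pseudogenes made up 12 of the 42 genes that passed between AKI and healthy plasma (28.6%), against 82 or 0.867% of 9461 tested genes (two-sided Fisher's exact p = 6.99e-16). The 9461 leave out XIST, TSIX and Y-linked genes. Of the 12 pseudogenes 7 were lower in AKI. For the 10 with a tested parent gene the log2 differences of pseudogene and parent lay a median of 2.96 apart, the parents' median log2 difference was 0.20, and 1 parent passed. RPL7P9 differed by -2.95 ± 0.26 and its parent RPL7 by 0.54, and EEF1A1P5 by -2.52 ± 0.26 and EEF1A1 by -0.09. The rule written beforehand counted a median of at least 1 toward reads of parent genes placed differently in the 2 cohorts. But random tested genes in place of the parents gave a median of 2.83 (2.32 to 3.57 in 95% of 10000 draws), so pseudogenes picked for passing would lie as far from most genes. The test decides nothing, and the cause stays open, the library names of the cohorts differing in marks of read trimming too.

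Chance was unlikely, though not excluded with 40 or 100 splits and unlabelled donors, for the counts of passing genes in 7 comparisons. There the real grouping gave the most genes of all splits drawn. It gave 4141 in healthy fluids (highest other 244 of 100 splits), 7952 in AKI fluids (220 of 40), 3393 over time in HSCT plasma (66 of 40), 1510 for D0 against PR (62 of 40), 4048 for E against D0 (921 of 40), 718 for E against PR (363 of 40) and 1814 for PR against healthy plasma (1190 of 100). The splits did not make chance unlikely for AKI against healthy urine, where 14 of 100 gave at least the real 22 (highest other 653). Nor did they for plasma, where 7 of 100 gave at least 42 (1231). Some structure among these libraries other than diagnosis is therefore likely. With 0 genes in the real grouping every split gives at least as many, so the splits decide nothing for 6M against PR (40 of 40, highest other 4), TP2 against TP1 in AKI urine (100 of 100, 61) and plasma (100 of 100, 1), or the difference of changes (40 of 40, 353).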
